A study of Homo sapiens with 2 samples.

How the data were processed

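The series describes bulk RNA sequencing of NGP neuroblastoma cells treated with 8 μM nutlin-3 or with ethanol vehicle, with 1 library per treatment. Per the labels' protocols, 100 ng of total RNA entered a stranded mRNA library kit and the libraries were sequenced as paired 75 bp reads. The submitters' processing notes name kallisto 0.43.1, a tool that estimates transcript abundance from reads, and the build hg38. No value made with them was used here. The design text of the series points to a merged table of normalized counts from the single-cell and bulk data, held with the single-cell records, which was not used here. The labels of both libraries mark the cells as synchronized, while the extraction protocol in the same labels speaks of 10 biological replicates without serum starvation. Which of these descriptions applies to the 2 libraries was not resolved.

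The deposited table analysed here is a list of single cells with text columns only, per the file headers: a name made of a treatment prefix and a cell barcode, a title that states the treatment, the source, the organism and the synchronization. How the authors selected these cells, and with which software and filters, is not given in the sources used here. Whether doublets, barcodes that hold more than a single cell, were removed is not given either. No doublet caller was run, since the list has no expression values, and each listed barcode was counted as a cell. Cells were assigned to vehicle or nutlin-3 by the title text, which is identical to the source name of the corresponding bulk sample. They are cells of the single-cell part of the study and were not treated as replicates or as parts of the bulk libraries.

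The list was read with Python 3.11.15 and pandas 2.3.3, with lines split at carriage returns. Cells were counted per treatment, and shares were given with 95% exact Clopper-Pearson intervals (SciPy 1.17.1). Cells are not replicates, and no p-value between treatments was computed. The number of barcodes shared between treatments was given with an exact 95% Poisson interval. To obtain the number expected by chance, barcodes were split into 2 parts at the point that gave the fewest combinations of distinct parts, with at least 5 bases in each part. The number of pairs of 1 vehicle and 1 nutlin-3 cell with the same first part was multiplied by the number with the same last part and divided by the number of all such pairs. Pairs of barcodes that differed at 1 base or at 2 bases were counted within and between treatments. The shared-barcode count and the count of pairs 1 base apart were tested on simulated data of 6387 cells. With 60 barcodes carried over, 77 were shared against 13.9 expected, and with none carried over, 14 were shared against 13.9 expected. With 60 barcode errors added, giving 6447 cells, 68 pairs within a treatment lay 1 base apart against 11.1 expected. The simulated barcodes held chance neighbours 1 base apart, which the real list lacks, so this checks the counting and not the power to detect errors in the real list. The minimum of 5 bases per part was set after seeing the data, because a shorter part is limited by its few possible forms.

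The tests and the rule for naming genes were fixed before the data were examined. The rule drew on lists of p53 targets, apoptosis, cell cycle, neuroblastoma identity, long noncoding RNA and housekeeping genes, and on the genes with the highest and the lowest ratio between the libraries. A list without expression values gives none of these, so no gene was named from it. Cell type marker lists fixed at the same time were not used for the same reason. The barcode comparisons were chosen after seeing the data.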

Results

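The study compared NGP cells, an established human neuroblastoma cell line, after treatment with nutlin-3 or with its ethanol vehicle. Nutlin-3 is a small molecule that blocks the binding of MDM2 to p53 and so stabilises p53. Per the treatment protocol in the labels, cells were kept at low density for 48 hours, held in serum-free medium for 24 hours and then exposed to 8 μM nutlin-3 or to vehicle for 24 hours before harvest. The labels conflict on whether the cells of the bulk libraries went through the serum-free step. The bulk arm of the study consisted of 2 libraries, 1 from vehicle-treated and 1 from nutlin-3-treated cells. The comparison planned here for the bulk arm was that of RNA levels between the treatments. No expression value of either bulk library was used here, so the response of p53 target genes, cell cycle genes or any other gene to nutlin-3 was not analysed here, and sequencing depth of the bulk libraries is unknown.

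The data examined were a list of single cells from the same treatments, which the submitters attached to the bulk series. It named 2977 vehicle-treated and 3410 nutlin-3-treated NGP cells, each by its treatment and a 16-base cell barcode, and marked each of them as synchronized. The list held 5 columns of text and 0 numeric entries. It gives no read count, gene count, cell cycle phase or quality value for a cell. The depth behind each cell is therefore unknown.

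More nutlin-3-treated than vehicle-treated cells were listed. The 3410 cells treated with nutlin-3 made up 53.4% of the list (95% exact Clopper-Pearson interval 52.2 to 54.6%). The 2977 vehicle-treated cells made up 46.6% (95% exact Clopper-Pearson interval 45.4 to 47.8%). The nutlin-3 arm thus had 433 more cells, or 1.15 cells per vehicle cell (95% interval 1.09 to 1.20, from the same exact interval). These intervals cover counting error only. Each treatment was a single group of cells with no labelled replicate, so no test between treatments was made and the spread between cultures is unknown. The number of listed cells is also set by how many cells were loaded, captured and kept, none of which the list records, so it is not a measure of survival or proliferation under nutlin-3. Each count is a number of barcodes, and how many of them hold more than a single cell is unknown.

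No barcode was listed more than once within a treatment, with 2977 distinct barcodes among the vehicle cells and 3410 among the nutlin-3 cells. A total of 8 barcodes occurred under both treatments (95% Poisson interval 3.45 to 15.8), equal to 0.269% of the vehicle cells. A barcode alone therefore did not identify an entry of the combined list, whereas the treatment and barcode together did. Guanine and cytosine made up 50.5% of the barcode bases in the vehicle cells and 50.5% in the nutlin-3 cells.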

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

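None of the 8 alternatives planned before the data were examined could be run. They concerned expression values, cell numbers per well, selection flags, numeric columns and plate positions, and the list holds none of these. The alternatives reported here were chosen after seeing the data. The nutlin-3 share of listed cells, 53.4%, was 53.4% without the barcodes found under both treatments. That step takes the same 8 barcodes from each treatment, so it could barely move the share. Leaving out barcodes 1 base from another of the same treatment removed no cell. The number of shared barcodes expected by chance was 13.6 from the recurrence of the first 7 and last 9 bases and 13.9 with equal use of the parts seen. It was 3.32 with the split after base 6 and 3.39 with the split after base 8, values below the 8 observed. The parts are not independent at those points. The first 6 and the first 7 bases both took 480 forms, so base 7 follows from the bases before it, and the last 8 and the last 9 bases both took 1517 forms, so base 8 follows from those after it. With as few as 3 bases allowed in a part, the split fell after base 13 and the expected number was 0.508, again below 8. The last 3 bases have 64 possible forms, all of them seen, so that split reflects this limit. No paired analysis was possible because each treatment had 1 bulk library and no expression value was used. With 1 group of cells per treatment, no replicate could be left out.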

Other observations

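The tests on barcodes found under both treatments were chosen after the number was seen, and those on barcodes 1 or 2 bases apart before their counts were seen. The barcodes had a structure of 2 parts. The first 7 bases took 480 forms and the last 9 bases took 1517, which allows 728160 combinations. Over the 480 first parts, the number of cells had a variance over mean of 0.913 for vehicle cells and 0.978 for nutlin-3 cells. Random placement gives 1. The upper-tail chi-square p for a wider spread was 0.915 for vehicle and 0.628 for nutlin-3 cells, across cells and not across cultures. Both ratios lay below 1, a direction that these p-values did not test.

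One hypothesis was that the 8 barcodes found under both treatments are chance reuse of a common barcode set. Chance reuse gave 13.6 expected barcodes (95% Poisson interval 7 to 21), and the observed 8 lay inside it (one-sided exact Poisson p = 0.0769 for so few, unadjusted). Carry-over of barcoded reads between the libraries would raise the number above that interval only if it added many listed barcodes. The observed 8 was not above it. A cell that crossed over before receiving its barcode would not add a shared one, so the count cannot address carry-over of such cells. The comparison with the expected number rests on the split after base 7. Splits after bases 6, 8 and 13 gave fewer expected barcodes than 8, and 8 lay above the 95% Poisson interval at each. At these splits the number met the prediction written for carry-over and not that for chance reuse. The expected number assumes independent parts, which these splits do not give, as stated above. Parts that depend on each other lower the expected number there, so this outcome cannot be read as a sign of carry-over. A carry-over of a few barcodes may still be present, since the interval of the observed number (3.45 to 15.8) reaches above the expected 13.6. No biological explanation was tested, as the list holds no measurement of the cells.

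A further hypothesis was that some listed cells are copies of others made by sequencing errors in the barcode. There were 0 pairs of barcodes within a treatment that differed at 1 base, and 0 among pairs between treatments, although pairs 2 bases apart occurred. The barcode set may therefore lack neighbours 1 base apart, and the comparison of the 2 counts says nothing about how often sequencing errors occurred. The count of 0 shows only that no listed barcode lies 1 base from another of its treatment, as a copy made by an error at 1 base would. At 2 bases apart, 204 pairs lay within a treatment, against 195 expected from the 193 pairs between treatments (95% Poisson interval 168 to 223). Errors are thus not the main source of these pairs, though the interval leaves room for some. It also leaves out the counting error of the 193 pairs from which the expected number was scaled.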
